A study of Homo sapiens with 4 samples.

How the data were processed

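Bisulfite sequencing libraries of genomic DNA were prepared with a methylation capture kit from 4 samples of the H9 line, per the labels' protocols, which state a conversion of 99% in every library from spiked-in unmethylated phage DNA. The reference build was hg19 (GRCh37), per the submitters' processing notes. The aligner, the methylation caller and the handling of duplicate reads are not given in the sources used here. The authors deposited 1 table per library with a row for each cytosine and strand. Per the file headers, its total, context and methylated coverage are raw read counts, and the deposited methylation level is a fraction. On every row that fraction equalled methylated over context coverage to within 5e-07. The minus strand held 82.3 to 83.9% of the rows. No table held a row with 0 methylated reads, although rows with 1 read were present and all of these stood at 100%. A missing row therefore means either no coverage or no methylated read, levels near 0 are raised by selection, and the selection is stronger where coverage is low.

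Cytosines were keyed by chromosome, position and strand, and the 2 strands of a CpG were kept apart. Chromosome Y was left out. The main set held the cytosines with at least 10 reads (context coverage) in all 4 libraries, with medians of 18, 20, 18 and 28 reads in WT primed, KO primed, WT naive and KO naive. Of these cytosines 2.48% had over 100 reads on average and took 23.8 to 29.6% of the reads; such sites can lie in repeated sequence and their position is uncertain. Levels were averaged with equal weight per cytosine. Single cytosines were compared by two-sided Fisher's exact tests on methylated and unmethylated reads with Benjamini-Hochberg adjustment, called at an adjusted p under 0.05 and a difference of at least 25 percentage points. The 1 kb tiles needed at least 5 cytosines, a mean difference of at least 25 points and at least 80% of the cytosines moving that way; this is a rule of size without a p-value. With 1 library per group, the comparisons of single groups carry no p-value between conditions. The naive and primed states were also compared over both genotypes as 2 pairs by an exact two-sided permutation test within pairs, which was added after seeing the data and cannot give a p below 0.5. Shares have Wilson 95% intervals and counts exact Poisson 95% intervals, which cover counting error only. The mean levels of the libraries were also pooled over reads, with a Wilson 95% interval of 65.88 to 65.94% in WT primed.

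The tests, thresholds and rule for naming regions were fixed before the data were examined. The plan was to use windows around transcript starts and lists of genes if an annotation of the same build was at hand, and 1 kb tiles otherwise; an hg19 annotation was not used here, so tiles took the place of promoters and no gene list was tested. The gene table at hand was of another build, and its coordinates were not used. The rule named, for each comparison, the 10 tiles with the largest decrease and the 10 with the largest increase among those passing the rule of size with at least 10 cytosines. The text gives a selection of these tiles, and ranges over those ranked. Alternatives planned were coverage minimums of 5 and 20 reads, read-weighted levels, each library's own cytosines, a difference of 50 points, 10 reads drawn per cytosine in every library, and at least 10 cytosines per tile. Added after seeing the data were a limit of 100 reads, merged strands, filling in, and scaled reads, as well as the bins of primed level on the mean of the primed libraries and on the primed library of the other genotype, the runs of adjacent tiles, the overlap of tile lists, the count of X tiles, the alternatives for X and the 1 Mb windows. The planned classes of CpG density used the number of measured CpGs within 250 bp. Filling in gave a cytosine that was unlisted in one library, and listed in another, 0 methylated reads at the coverage of its nearest listed neighbour of the same strand within 25 bp (the lower of both sides). Among listed cytosines whose neighbours predicted at least 10 reads, 95.6 to 97.1% had at least 10. Scaling divided the read counts by the variance ratio between the strands of CpGs at levels of 20 to 80%, which was 3.81, 3.98, 3.21 and 2.55 in WT primed, KO primed, WT naive and KO naive and can hold true differences between strands.

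The cytosine test and the tile rule were tested on simulated data with independent reads at the real depths of each comparison, with 411226 cytosines of which 20000 were lowered by 50 points and as many by 30. For WT naive against WT primed, 46.6% of the former and 11.3% of the latter were called. The shares were 64.6% and 19.8% for KO naive against KO primed, 49.03% and 12.6% for KO against WT primed, and 54.8% and 12.4% for KO against WT naive. Unchanged cytosines made up 0.805 to 1.78% of the calls. The real reads varied more between strands than independent reads would, so this share does not carry over to the real calls. The lowered cytosines were drawn from those at high levels, in equal number for every comparison. Between the primed libraries only 1327 lower and 2478 higher cytosines were called, so the recovered shares may be too high for KO against WT. Simulated tile differences departed from the true ones with an SD of 3.72 to 4.69 points. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.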

Results

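DNA methylation was measured by bisulfite sequencing of captured genomic DNA from H9, an established human embryonic stem cell line, in 4 libraries. The libraries were wild-type (WT) cells in the primed state in basal medium, B3GALT5-knockout (KO) cells in the primed state in basal medium, WT cells converted to the naive state in 5iLAF medium, and KO cells converted to the naive state in 2iLAF medium. B3GALT5 is a galactosyltransferase of glycosphingolipid synthesis. Each of the 4 groups held 1 library, so no difference between groups had a replicate check. The libraries listed 2109788 (WT primed), 2204054 (KO primed), 2018895 (WT naive) and 2340330 (KO naive) CpG cytosines, at a median of 7, 8, 8 and 13 reads each. Their summed reads were 24570785, 28450230, 23916547 and 40697882, in the same order. A cytosine was listed only where at least 1 read was methylated, so sites without methylation were not seen and every level below is that of cytosines with some methylation. Levels were compared over the 396398 autosomal and 14828 chromosome X cytosines that had at least 10 reads in all 4 libraries. Regions are given as 1 kb tiles in hg19 coordinates, and gene names were not assigned. The targeted gene itself was not located on these coordinates, so the knockout labels were not checked against it.

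The first comparison asked how the methylation of WT cells differed between the naive and the primed state. The mean autosomal CpG level was 76.6% in the primed and 54.05% in the naive library, and so decreased by 22.6 percentage points. The SD across cytosines was 26.02 points in the primed and 26.6 points in the naive library. The level was lower in the naive library at 80.7% of the cytosines and on each of the 22 autosomes, where the mean difference ranged from -24.7 points on chromosome 14 to -20.7 points on chromosome 9. In the primed library 44.7% of cytosines were at 90% or above (Wilson 95% interval 44.6 to 44.9%). In the naive library this share was 10.5% (10.4 to 10.6%), while the share at 20% or below was 13.99%, against 5.70% in the primed library. These intervals cover counting error only, here and below.

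**Figure D1:**
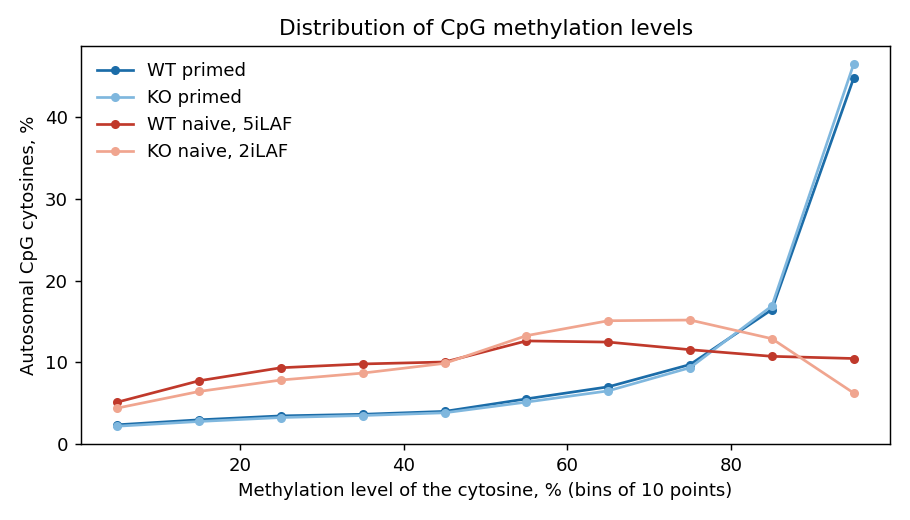
Share of the 396398 autosomal CpG cytosines (y axis, %) in bins of methylation level (x axis, %) for each library; each point is 1 bin of 1 library. Both primed libraries peak in the top bin, at 44.7% and 46.5% of cytosines, and both naive libraries spread over intermediate levels.

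At the scale of 1 kb tiles, 7704 of 20581 tiles (37.4%) were lower in the WT naive library by at least 25 points, with at least 80% of their cytosines moving that way, and 105 were higher. The largest drop among tiles with at least 10 cytosines lay on chromosome 4, 640001 to 641000, where the mean level was 97.4% ± 5.58 in the WT primed and 9.86% ± 5.89 in the WT naive library (SD over 20 cytosines). The tile on chromosome 4, 187125001 to 187126000 went from 98.1% ± 4.68 to 12.1% ± 6.13 over 15 cytosines. The tile on chromosome 22, 46008001 to 46009000 went from 96.3% ± 4.70 to 11.99% ± 5.54 over 13 cytosines. Further down the ranking, the tile on chromosome 3, 181413001 to 181414000 went from 93.1% ± 6.69 to 10.5% ± 8.08 over 30 cytosines. In the 10 tiles with the largest drops, the level lay between 90.98% and 98.3% in the primed library and between 9.86% and 18.2% in the naive library. The rare gains led with the tile on chromosome 17, 4763001 to 4764000, at 18.1% ± 12.5 in the primed and 68.2% ± 19.05 in the naive library over 17 cytosines. Next were tiles on chromosome 5, 153873001 to 153874000, from 7.40% ± 4.22 to 50.6% ± 23.8, and on chromosome 18, 42324001 to 42325000, from 22.1% ± 12.7 to 58.97% ± 17.1. Of the 10 largest gains, 2 lay on chromosome X, the larger of them on chromosome X, 106750001 to 106751000, from 24.1% ± 13.8 to 60.3% ± 16.1. Over the tiles ranked this way the mean coverage was 17.03 to 34.3 reads per cytosine. The tiles were ranked on the libraries they describe, so their differences are extremes of these libraries.

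Two-sided Fisher's exact tests on the reads of single cytosines, with Benjamini-Hochberg adjustment, called 109791 of 411226 cytosines lower and 3405 higher at a difference of at least 25 points. These tests compare 2 libraries, not the conditions, and take reads as independent molecules. The 2 strands of the same CpG differed within a library by 2.55 to 3.98 times the binomial variance, and with read counts scaled down by that factor 1492 lower and 3 higher calls were left. The factor came from the 32834 CpGs measured on both strands, of which 10420 to 19332 per library lay at 20 to 80%. It was applied to all cytosines, and whether it holds for the others was not tested. With cytosines that one library did not list filled in at 0 from neighbouring coverage, the mean autosomal level decreased by 20.9 points, and 8197 tiles were lower and 281 higher. With at least 20 reads per cytosine, 0.278% of 4668 tiles were higher, against 0.510% at the minimum of 10 reads.

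The same comparison was made in KO cells, whose naive library came from 2iLAF medium. The mean autosomal level was 77.7% in the KO primed and 55.7% in the KO naive library, and so decreased by 21.9 points. The SDs across cytosines were 25.5 and 24.8 points. The level was lower in the naive library at 86.1% of cytosines and on all 22 autosomes, with mean differences from -23.7 points on chromosome 14 to -19.8 points on chromosome 9. By the same size rule, 7031 of 20581 tiles (34.2%) were lower and 44 higher in the KO naive library. Among tiles with at least 10 cytosines the largest drop lay on chromosome 19, 53088001 to 53089000, from 96.8% ± 6.66 to 5.29% ± 2.70 over 15 cytosines. Another tile of the same chromosome, on chromosome 19, 17972001 to 17973000, went from 97.3% ± 4.89 to 15.7% ± 8.003, and the tile on chromosome 13, 113420001 to 113421000 from 96.2% ± 5.94 to 15.3% ± 12.2. The tile on chromosome 22, 46008001 to 46009000 was among the 10 largest drops of both genotypes and stood at 93.4% ± 6.98 in the KO primed and 12.1% ± 7.40 in the KO naive library. The tile with the largest gain in WT cells was also first in KO cells: on chromosome 17, 4763001 to 4764000 the level was 13.9% ± 7.34 in the KO primed and 79.3% ± 14.5 in the KO naive library. Further gains lay in adjacent tiles of chromosome 4 from 13524001, where the first tile went from 24.02% ± 6.12 to 66.4% ± 6.10, and on chromosome 9, 107157001 to 107158000, from 21.3% ± 16.3 to 60.8% ± 11.1. The 8 largest increases among such tiles ranged from 25.95 to 65.5 points and the 10 largest decreases from -74.6 to -91.5 points. The mean coverage of the tiles ranked this way was 15.4 to 43.5 reads per cytosine. Two-sided Fisher's exact tests on the reads of single cytosines, with Benjamini-Hochberg adjustment, called 112602 of 411226 cytosines lower and 1612 higher at a difference of at least 25 points. With reads scaled by the disagreement between strands, 2383 lower and 1 higher calls were left, and with sites filled in at 0 the mean autosomal level decreased by 20.5 points with 84 tiles higher. With at least 20 reads per cytosine, 0.0428% of 4668 tiles were higher, against 0.214% at the minimum of 10 reads.

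Both genotypes were then set side by side; these comparisons share no library. Over both, the autosomal naive-minus-primed difference was -22.3 points ± 0.444 (SD, n = 2 pairs), lower in 2 of 2 pairs, with p = 0.5 in an exact two-sided permutation test within pairs, the smallest p that this number of pairs can give. The naive medium differed between the pairs. Across 20581 tiles the naive-minus-primed differences of WT and KO cells had a Pearson r of 0.635 and a Spearman rho of 0.585, a correlation across tiles, which are not independent replicates. Of the 7704 tiles lower in WT and the 7031 lower in KO naive cells, 4744 were the same tiles, where independent lists would share 2632. Of the 105 and 44 tiles that were higher, 14 were shared (exact Poisson 95% interval 7.65 to 23.5), against 0.224 for independent lists. At single cytosines, 52696 were called lower in both, against 30063 for independent lists and 34181 for lists independent within 5-point bins of the primed level. The tile baselines were not matched on primed level. No baseline was matched on read depth, which also limits which cytosines can be called. Tiles were also grouped by primed level, in bins chosen after the data were seen. Tiles at 90 to 100% in the mean of the primed libraries differed by a mean of -26.8 points in WT and -24.2 points in KO cells between naive and primed, and 12.8% of these 6032 tiles were still at 80% or above in both. The mean differences were -25.9 and -24.5 points in the 5627 tiles at 80 to 90%, -15.03 and -16.6 points in the 2437 tiles at 40 to 60%, and 6.64 and 1.55 points in the 474 tiles at 0 to 20%. These bins use the primed levels that the differences subtract, which by itself moves the differences of the low bins up and of the high bins down, and a low level leaves little room to fall. Binned on the primed library of the other genotype, which the difference does not use, the means in WT and KO cells were -24.9 and -22.7 points at 90 to 100%, -26.4 and -24.8 points at 80 to 90%, -15 and -17.1 points at 40 to 60%, and 2.77 and -3.51 points at 0 to 20%.

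**Figure D2:**
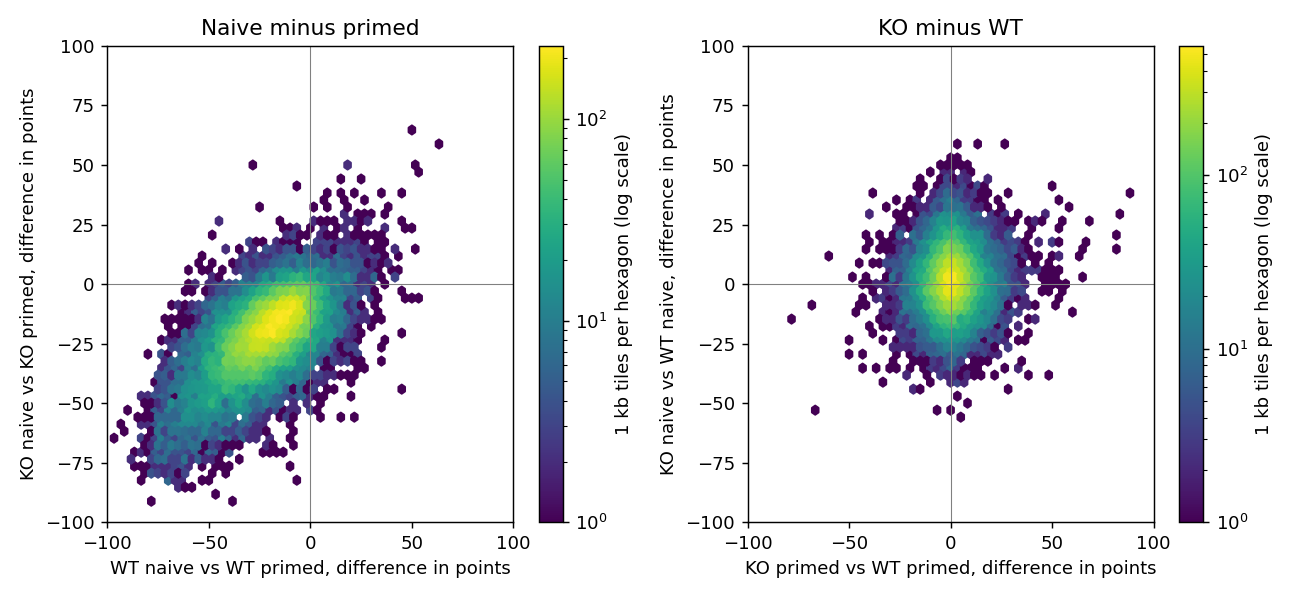
Differences in mean methylation of 20581 tiles of 1 kb, in percentage points, with colour giving the number of tiles per hexagon on a log scale. Left, naive minus primed in WT (x axis) against KO (y axis), with medians of -20.1 and -19.3 points and r = 0.635; right, KO minus WT in the primed (x axis) against the naive state (y axis), with medians of 0.654 and 1.31 points and r = 0.0341.

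The primed state held 1 KO and 1 WT library, so the knockout cannot be told apart from other differences between them. KO primed cells were compared with WT primed cells, both in basal medium. Their mean autosomal levels were 77.7% and 76.6%, higher by 1.04 points in the KO library, with the same direction on all 22 autosomes (range 0.668 to 1.71 points). Weighted by reads the difference was 0.582 points. By the rule of size, 269 of 20581 tiles were higher and 142 lower by at least 25 points in KO cells. With at least 20 reads per cytosine, 39 of 4668 tiles were higher and 20 lower, or 0.835% and 0.428% against 1.31% and 0.690% at the minimum of 10 reads. Among tiles with at least 10 cytosines the largest gain lay on chromosome 2, 95692001 to 95693000, at 10.2% ± 8.13 in WT and 90.9% ± 12.7 in KO primed cells over 24 cytosines. The tile on chromosome 16, 66612001 to 66613000 stood at 19.2% ± 12.3 in WT and 87.2% ± 17.3 in KO cells. On chromosome 13, 58207001 to 58208000 the levels were 24.4% ± 15.2 and 91% ± 5.48, and on chromosome 1, 50513001 to 50514000 they were 26.4% ± 29.8 and 92.8% ± 14.7. On chromosome 20, 30135001 to 30136000 the levels were 10.7% ± 4.39 and 74.97% ± 9.32. Gains also ran over neighbouring tiles: 8 runs of at least 2 adjacent tiles were higher in KO cells, and the longest covered 4 tiles on chromosome 2, 63283001 to 63287000, at a mean of 11.4% in WT and 71.9% in KO cells over 42 cytosines. Runs that were lower in KO cells numbered 2, both on chromosome X, at 38662001 to 38664000, with means of 33.3% in WT and 5.11% in KO cells, and at 48379001 to 48381000, with 66.97% and 24.3%. The largest drop lay on chromosome 18, 70210001 to 70211000, at 75.6% ± 18.4 in WT and 29.1% ± 16.2 in KO cells, followed by chromosome 2, 43903001 to 43904000, at 92.4% ± 14.4 and 48.6% ± 16.4. The next tiles were both on chromosome X, at 48380001 to 48381000, with 68.6% ± 9.89 in WT and 25.5% ± 6.81 in KO cells, and at 99891001 to 99892000, with 70.9% ± 11.7 and 31.1% ± 4.93. The 10 largest increases among such tiles ranged from 53.8 to 80.8 points and the 10 largest decreases from -32.5 to -46.5 points. The mean coverage of the tiles ranked this way was 14.8 to 28.1 reads per cytosine. Two-sided Fisher's exact tests on the reads of single cytosines, with Benjamini-Hochberg adjustment, called 1327 of 411226 cytosines lower and 2478 higher at a difference of at least 25 points. With reads scaled by the disagreement between strands the counts were 25 and 0 by the same test (307 and 714 at an unadjusted p under 0.05), and with 10 reads drawn per cytosine 0 and 0 (4078 and 6036 unadjusted). The unadjusted counts are not corrected for 411226 tests and were not taken as differences. With so few reads only very large differences, in sufficient number, can pass the adjustment. The low adjusted counts under these 2 settings therefore do not count against a difference.

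In the naive state, KO cells in 2iLAF were compared with WT cells in 5iLAF; genotype and medium differed together here and cannot be told apart. The mean autosomal levels were 55.7% and 54.05%, higher by 1.67 points in the KO library and in the same direction on all 22 autosomes (range 0.949 to 3.24 points, the highest on chromosome 21). Over each library's own cytosines the difference was 0.611 points. By the rule of size, 527 of 20581 tiles were higher and 265 lower in the KO naive library. With at least 20 reads per cytosine, 44 of 4668 tiles were higher and 19 lower, or 0.943% and 0.407% against 2.56% and 1.29% at the minimum of 10 reads. Among tiles with at least 10 cytosines KO exceeded WT most on chromosome 10, 38691001 to 38692000, at 12.9% ± 5.02 in the WT naive and 72.4% ± 9.90 in the KO naive library over 14 cytosines, where both primed libraries were at 85.6% and 87.8%. Tiles on chromosome 14, 38679001 to 38680000 and on chromosome 14, 65009001 to 65010000 stood at 39.96% ± 23 and 27.3% ± 10.6 in the WT naive and at 86.5% ± 6.38 and 72.6% ± 9.08 in the KO naive library. Their primed levels were 96.4% and 90.6% in WT and 96.2% and 90.5% in KO cells. These tiles and the one on chromosome 10 thus fell less from primed to naive in KO than in WT cells. KO stood furthest below WT on chromosome 18, 42324001 to 42325000, at 58.97% ± 17.1 in WT and 21.6% ± 10.5 in KO naive cells, and on chromosome X, 106750001 to 106751000, at 60.3% ± 16.1 and 23.6% ± 9.67. Both tiles were among the gains of WT cells, from primed levels of 22.1% and 24.1%. The KO primed levels were 43.7% and 23.9%, so the KO level fell on chromosome 18 and hardly changed on X. The 10 largest positive KO-minus-WT differences among such tiles ranged from 39.7 to 59.5 points. The 10 largest negative ones ranged from -31.02 to -37.3 points. The mean coverage of the tiles ranked this way was 13.96 to 88.96 reads per cytosine. Two-sided Fisher's exact tests on the reads of single cytosines, with Benjamini-Hochberg adjustment, called 2167 of 411226 cytosines lower and 3748 higher at a difference of at least 25 points. With reads scaled by the disagreement between strands the counts were 30 and 0 by the same test (1340 and 2401 at an unadjusted p under 0.05), and with 10 reads drawn per cytosine 0 and 0 (5899 and 8486 unadjusted). Here too the unadjusted counts are not corrected for 411226 tests and were not taken as differences. The low adjusted counts with scaled or drawn reads again follow largely from the few reads and do not count against a difference. The KO-minus-WT differences of the naive and the primed state, which share no library, had a Pearson r of 0.0341 and a Spearman rho of 0.0203 across 20581 tiles. Of the 269 tiles higher in KO primed cells, 20 were also among the 527 higher in KO naive cells (exact Poisson 95% interval 12.2 to 30.9), against 6.89 for independent lists, and of the 142 lower tiles 12 were shared (6.20 to 20.96), against 1.83. Tiles called in opposite directions in the 2 states numbered 14, against 7.10 for independent lists. Overlap thus exceeded that of independent lists in the same and in opposite directions.

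Chromosome X stood below the autosomes in every library. Its mean level was 62.9% in WT primed, 63.5% in KO primed, 43.2% in WT naive and 43.6% in KO naive cells, while the lowest autosome was at 72.03%, 73.1%, 51.4% and 53.1%. From primed to naive its difference was -19.7 points in WT and -19.8 points in KO cells. Weighted by reads, these differences were -10.02 and -11.7 points. KO minus WT on X was 0.578 points in the primed and 0.468 points in the naive state, and turned to -2.04 and -3.72 points when weighted by reads. A 1 Mb window on X, 115000001 to 116000000, held 231 cytosines at a mean of 691 reads, with KO minus WT at -10.1 and -13.95 points. With at most 100 reads per cytosine the differences on X were 0.708 and 0.602 points, and with each library's own cytosines -0.894 and -2.12 points. Whether this window accounts for the change of sign was not tested. Where more than 30 measured CpGs lay within 250 bp, the WT primed level was 51.1% on X and 72.8% on autosomes, and where at most 5 did it was 72.4% and 80.2%. At the dense sites the naive-minus-primed difference was -11.5 points on X and -19.5 points on autosomes in WT, and -11.3 and -18.6 points in KO cells. Where at most 5 CpGs lay within 250 bp, it was -25.1 and -24.5 points in WT, and -27.1 and -23.7 points in KO cells. With unlisted cytosines filled in at 0 the WT primed level at dense sites was 45.5% on X and 60.9% on autosomes, and the naive-minus-primed difference there was -12.4 and -15.5 points in WT and -10.1 and -15.7 points in KO cells. Filling in thus lowered the WT primed level at dense sites more on autosomes than on X. It restores only cytosines listed in at least 1 library. The size of the gap between X and autosomes at dense sites therefore depends on the selection for methylated reads. Between the primed libraries, 27 X tiles were lower and 35 higher in KO cells out of 833, or 7.44% of X tiles, against 1.77% of autosomal tiles. Between the naive libraries 45 X tiles differed, or 5.40%, against 3.78% of autosomal tiles. Of these, 22 were lower in KO cells (2.64% of X tiles, against 1.23% of autosomal tiles) and 23 higher (2.76% against 2.55%). The read depth of X relative to the autosomes was 0.977 (KO primed), 0.935 (WT naive) and 0.922 (KO naive) times that in the WT primed library, and single autosomes ranged from 0.931 to 1.08 times.

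**Figure D3:**
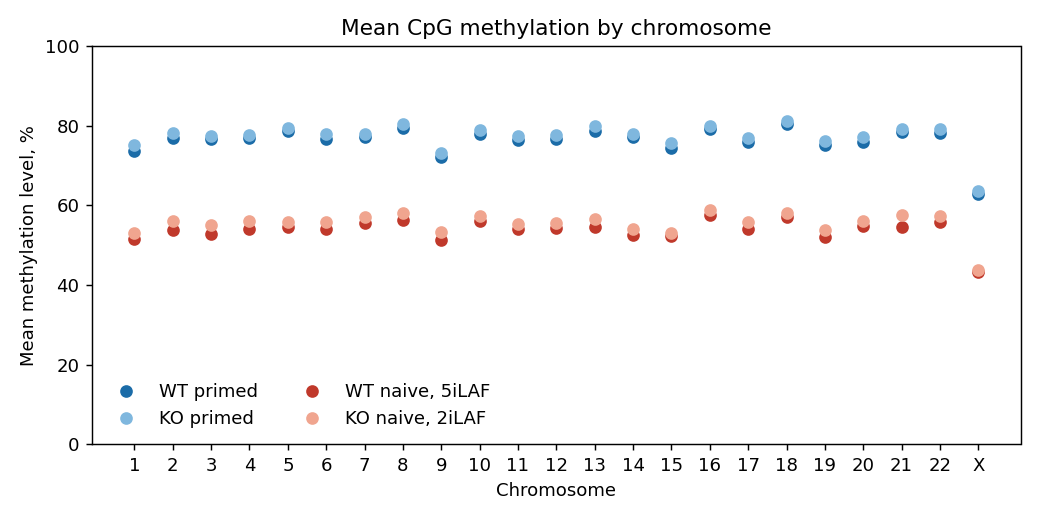
Mean CpG methylation level (y axis, %) of each chromosome (x axis); each point is 1 library. Every autosome of the naive libraries lies below every autosome of the primed libraries, and X is lowest in each library (62.9%, 63.5%, 43.2% and 43.6%).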

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

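The test of agreement between strands was chosen after that disagreement had been seen, and the correlation test after correlations over all tiles had been seen. Filling in was also added after the data were seen, with the bounds of its test set before its value was. 7 tiles moved in opposite directions from the primed to the naive state in the 2 genotypes, each past the rule of size; the difference was not tested, since each group held 1 library, and the tiles hold few cytosines. Independent lists would give 52.3 such tiles, and at single cytosines 87 were called lower in WT and higher in KO naive cells, against 430.4 for independent lists, and 227 the other way, against 932. These baselines do not take the primed level into account. A fall of 25 points needs a sufficient primed level and a rise needs room above it. Similar primed levels alone thus make opposite calls rare, and the lower counts do not by themselves show agreement between the genotypes. On chromosome 12, 127973001 to 127974000 (5 cytosines), the WT change was 25.96 and the KO change -32.6 points, a difference of -58.6 points. On chromosome 14, 72238001 to 72239000 (6 cytosines), the WT change was 36.6 and the KO change -32.3 points, a difference of -68.8 points. On chromosome 19, 58850001 to 58851000 (8 cytosines), the WT change was 27.8 and the KO change -34.98 points, a difference of -62.8 points. On chromosome 5, 491001 to 492000 (5 cytosines), the WT change was -28.9 and the KO change 48.7 points, a difference of 77.6 points. On chromosome 7, 27686001 to 27687000 (5 cytosines), the WT change was -44.9 and the KO change 25.5 points, a difference of 70.4 points. On chromosome 7, 151828001 to 151829000 (5 cytosines), the WT change was 34.1 and the KO change -26.7 points, a difference of -60.8 points. On chromosome X, 142723001 to 142724000 (5 cytosines), the WT change was 44.6 and the KO change -42.7 points, a difference of -87.3 points. The WT and KO primed levels already differed in all 7 tiles. In the order given they were 49.7% and 83.9%, 58.2% and 93.2%, 51.4% and 78.98%, and 56.7% and 18.2%. The last of them were 92.2% and 51.7%, 59.3% and 98.2%, and 13.1% and 60.97%. In each tile the genotype with the lower primed level rose and the other fell. The differences in change thus include the gap between the primed libraries.

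The lower methylation of both naive libraries was weighed against 2 technical explanations. With unlisted cytosines filled in at 0, the autosomal difference was -20.9 points in WT and -20.5 points in KO cells, against -22.6 and -21.9 points over listed sites. Filling in enlarged the set only from 396398 to 436793 cytosines. That is too few added sites for the difference to reach the bound set for missing rows. The test therefore could not decide, and missing rows stay open as a cause. Uniform over-conversion would lower all fully methylated regions by one factor, yet across 4193 tiles at 90% or above in both primed libraries the remaining levels in the naive libraries correlated at r = 0.712 (bootstrap 95% interval 0.696 to 0.728) and spread from 32.9% to 89.8% in WT (5th to 95th percentile). These values argue against a single factor only. A correlation over all tiles had been seen beforehand, and the interval takes tiles as independent. Over-conversion that varies between regions was not tested and stays open. The state of the cells stays open as a hypothesis, as do culture conditions and the single culture behind each library.

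More autosomal cytosines stood at 90% or above in the WT naive than in the KO naive library, by 4.22 percentage points. With 10 reads drawn per cytosine in both libraries the difference was 1.11 points, between the bounds of 1 and 2 points set for and against depth as the whole cause, which leaves depth open. The strands of a CpG at 10 reads each differed with an SD of 30.6 points in WT naive and 26.1 points in KO naive, a gap of 4.47 points; since the disagreement had been seen beforehand, this does not count for or against fewer independent molecules in the WT library, which stays open. A biological difference between genotypes or media stays open and was not tested.

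Tiles on chromosome X were over-represented among those that differed between the primed libraries, at 4.21 times the autosomal share (95% counting interval 3.23 to 5.40). Against autosomal tiles matched on primed level and number of cytosines the ratio was 3.13 (2.40 to 4.02), which argues against the intermediate levels of X as the whole cause. With at least 20 reads per cytosine it was 6.64 (3.72 to 10.9, 15 called X tiles), which argues against thin coverage. Between the naive libraries the ratio to the autosomal share was 1.43 (1.04 to 1.91), without matching on level. The called share of X tiles was 7.44% in the primed and 5.40% in the naive comparison, and that of autosomal tiles 1.77% and 3.78%. The lower ratio thus came with a higher autosomal share as well as a lower share on X. A candidate explanation that stays open is a difference between the primed cultures in the methylation of X; whether it comes with the knockout or with separate passaging could not be tested with 1 library per group.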

How the results depend on the processing

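Filling in, the limit of 100 reads, merged strands, scaled reads and all settings for X were chosen after the data were seen; the other settings were planned. All 4 differences in mean autosomal level kept their direction under the 6 alternatives run for them, and the levels themselves moved with the set of cytosines. The mean autosomal levels (in %, in the order WT primed, KO primed, WT naive and KO naive) were 80.7, 81.7, 58.1 and 59.3 with a minimum of 5 reads, then 64.6, 65.5, 45.1 and 46.96 with a minimum of 20 reads, then 65.9, 66.5, 49.3 and 50.8 with weighting by reads, then 72.6, 73.4, 51.5 and 52.1 with each library's own cytosines, then 70.9, 71.9, 49.97 and 51.4 with sites filled in at 0, then 77.4, 78.5, 54.6 and 56.3 with at most 100 reads. The differences (in points, in the order WT naive minus primed, KO naive minus primed, KO minus WT primed, KO minus WT naive) were -22.6, -22.4, 0.999 and 1.21 with a minimum of 5 reads, then -19.5, -18.6, 0.957 and 1.88 with a minimum of 20 reads, then -16.6, -15.7, 0.582 and 1.52 with weighting by reads, then -21.1, -21.3, 0.808 and 0.611 with each library's own cytosines, then -20.9, -20.5, 1.03 and 1.39 with sites filled in at 0, then -22.8, -22.2, 1.05 and 1.65 with at most 100 reads. The same differences on X were -19.96, -21.2, 0.244 and -0.979 with a minimum of 5 reads, then -16.7, -15.9, 0.0728 and 0.816 with a minimum of 20 reads, then -10.02, -11.7, -2.04 and -3.72 with weighting by reads, then -16.8, -18.02, -0.894 and -2.12 with each library's own cytosines, then -19.4, -18.8, 0.886 and 1.49 with sites filled in at 0, then -20.03, -20.1, 0.708 and 0.602 with at most 100 reads. Those from primed to naive kept their direction, and KO minus WT changed sign with weighting by reads and with own cytosines in both states, and with a minimum of 5 reads in the naive state. The counts of single cytosines, lower then higher for the same 4 comparisons, were 28664, 1054, 26570, 385, 839, 1366, 960 and 1664 with a minimum of 20 reads, then 63027, 1410, 42681, 377, 727, 1437, 1117 and 2125 with a difference of 50 points, then 15230, 204, 9431, 62, 0, 0, 0 and 0 with 10 reads drawn per cytosine, then 114511, 5954, 116545, 2424, 1638, 2947, 2863 and 4285 with sites filled in at 0, then 1492, 3, 2383, 1, 25, 0, 30 and 0 with reads scaled by the strands. With 10 reads drawn, Fisher's exact test at an unadjusted p under 0.05 would have called 4078 lower and 6036 higher cytosines between the primed and 5899 and 8486 between the naive libraries. With scaled reads 714 and 2401 would have been called higher. Such counts are not corrected for 411226 tests and were not taken as differences. Merged strands and the limit of 100 reads left all 8 counts within 1.5 times, as did the limit of 100 reads for the tiles. A minimum of 5 reads did so too, but over 907719 cytosines in place of 411226, and all 8 called shares changed by over 1.5 times: 16.2% against 26.7% for those lower in WT naive cells and 0.103% against 0.323% for those lower in KO primed cells. Cytosines lower in both naive libraries numbered 15784 with a minimum of 20 reads (8689 for independent lists), 2038 with 10 reads drawn per cytosine (349 for independent lists), 791 with reads scaled by the strands (8.65 for independent lists). These baselines were not matched on primed level or read depth. With 10 drawn reads only very large differences can be called, and with scaled reads mostly cytosines with many reads. Both limits restrict the 2 lists to the same kinds of site, so the excess does not by itself show shared loss at the same CpGs. The counts of tiles, in the same order, were 18838, 274, 18510, 83, 409, 790, 1130 and 1703 with a minimum of 5 reads, then 1365, 13, 1136, 2, 20, 39, 19 and 44 with a minimum of 20 reads, then 2374, 18, 2032, 8, 30, 64, 34 and 102 with at least 10 cytosines, then 8197, 281, 7456, 84, 173, 333, 322 and 592 with sites filled in at 0. The number of tiles measured changed from 20581 to 51144, 4668, 6799 and 24113. As shares of the tiles measured (in %), these were 37.4, 0.510, 34.2, 0.214, 0.690, 1.31, 1.29 and 2.56 as reported, 36.8, 0.536, 36.2, 0.162, 0.800, 1.54, 2.21 and 3.33 with a minimum of 5 reads, 29.2, 0.278, 24.3, 0.0428, 0.428, 0.835, 0.407 and 0.943 with a minimum of 20 reads, 34.9, 0.265, 29.9, 0.118, 0.441, 0.941, 0.500 and 1.5 with at least 10 cytosines, 33.99, 1.17, 30.9, 0.348, 0.717, 1.38, 1.34 and 2.46 with sites filled in at 0. Another minimum of reads or cytosines changes how many can be called, and scaled reads and 10 drawn reads hold fewer counts, which moves the counts by construction; the cause of the other shifts, those of the tile shares included, was not tested. The planned narrower window around transcript starts was not run, since tiles took the place of promoters. Depth limits which single cytosines can be called, and cytosines without a methylated read in every library stay unseen.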

Other observations

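Windows of 1 Mb with at least 100 cytosines, a scale chosen after the data were seen, and named after their values were seen, differed in the change from primed to naive. Over 1445 windows the mean change was -22.4 points (SD across windows 4.83) in WT and -21.9 points (4.10) in KO naive cells. The window on chromosome 5, 140000001 to 141000000 held 2416 cytosines and went from 86.3% to 43.5% in WT and from 85.9% to 50.2% in KO cells, among the 5 largest drops of both genotypes. The window on chromosome 13, 45000001 to 46000000 did so as well, from 82.9% to 40.4% in WT and from 80.6% to 43.2% in KO cells. Among the 5 windows least lowered in WT cells, the one on chromosome 12, 54000001 to 55000000 was at 39.8% in WT primed and 40.3% in WT naive cells, and at 40.1% and 34.7% in KO cells. Others of these 5, on chromosome 2, 176000001 to 177000000 and on chromosome 7, 27000001 to 28000000, changed by -4.16 and -4.67 points in WT and by -10.8 and -7.93 points in KO cells. The remaining windows, on chromosome 20, 26000001 to 27000000 and on chromosome 9, 1 to 1000000, changed alike in both genotypes. Their changes were -3.28 and -3.99 points in WT and -3.48 and -3.42 points in KO cells. Their primed levels were only 21.4% and 35.7% in WT and 23.6% and 35.1% in KO cells. These levels left less room to fall than in the windows with the largest drops. Their mean coverage was 79.6 and 65.4 reads per cytosine, against a median of 21.25 over all cytosines compared, so their position may be uncertain.

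Between the primed libraries, the window with the largest gain in KO cells was on chromosome 2, 63000001 to 64000000, at 50.7% in WT and 72.8% in KO cells over 144 cytosines, and the next on chromosome 1, 50000001 to 51000000, at 55.7% and 69.7%. Over all 1445 windows the mean KO-minus-WT difference was 1.09 points (SD 2.09). In the naive libraries the first of these windows was at 45.5% in WT and 51.8% in KO cells, and the second at 45.1% and 46.9%. Of tiles at 90% or above in both primed libraries, the share still at 80% or above in both naive libraries ranged from 10.7% on chromosome 14 to 19.8% on chromosome 16.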
